A study of Homo sapiens with 12 samples.

How the data were processed

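RNA sequencing measured polyadenylated transcripts in T98G and U251, a pair of established human glioblastoma cell lines. In each line, cells labelled PEPD-OE, which the series title explains as over-expression of PEPD, were compared with cells labelled NC, an abbreviation the labels do not expand. Each of the 4 groups held 3 replicates, 12 libraries in all. The labels do not say whether the replicates were separate cultures. If they were not, the p-values measure only the spread between these samples, which may be technical.

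Per the labels, mRNA was captured on oligo beads, the second cDNA strand was marked with dUTP so that the strand of origin was kept, and paired-end reads were sequenced on a NovaSeq instrument. The submitters' processing notes name FastQC, fastp, HISAT2, featureCounts, Subread and the genome build GRCh38, without versions or roles. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds raw counts per Ensembl gene for 63241 genes, 20573 of them without a symbol, with 1 column of whole numbers for each library. No normalization by the authors was found in these values. Columns were assigned to samples by the library names in the labels.

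Library totals ranged from 464056 to 924204 counts, with a median of 772232. A count of 3 in a library equalled 3.25 to 6.46 CPM (counts scaled to a library of 1e6). Symbols were taken from the deposited table. Chromosome positions, strands and exons came from GENCODE release 29, which held 58228 of the identifiers (92.1%) and with them 95.9% of all counts. A gene was said to overlap the opposite strand when any of its exons shared bases with an exon of a gene on the other strand. In the text the partner with such an exon is named in parentheses after the word opposite.

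Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, leaving 8 residual degrees of freedom. The contrasts were PEPD-OE minus NC in T98G, the same in U251, and the T98G change minus the U251 change. The two-sided p-values were adjusted by Benjamini and Hochberg over the 8773 genes tested, and a gene was called at an adjusted p under 0.05. Of these genes, 4115 had no exon overlap with the opposite strand, 4489 had one and 169 were not in release 29. Levels are given as mean CPM with the SD over 3 libraries. Log2 fold changes are given with a standard error (SE) derived from the test: their size divided by the square root of the F statistic. Where a group had few counts, this SE can lie below the counting error, so no interval should be built from it. The smallest two-sided p of an exact test of 3 against 3 is 0.1, so single values were not tested apart from the model. Where a group had 0 counts, the fold is a bound against 3 counts over the group. Where a called gene had 1 to 3 counts in a group, the ratio of scaled counts is given with its exact 95% counting interval. Such intervals and floors cover counting error only.

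In all, 39 gene lists were fixed before the data were examined, as were the contrasts, the thresholds, the rule for named genes and most of the alternative settings. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with PEPD taken out of every list and p-values adjusted over the lists. Beside it, camera with the correlation estimated for each list and fry were run. For each list the members called over all genes and those called when adjusted over the list alone were counted. Overlaps between the lines were tested with one-sided Fisher's exact tests, adjusted over all overlaps tested. Both the correlation between the lines and the Fisher tests are across genes, and genes are not independent replicates. The Fisher p-values treat related genes as separate and so overstate the evidence.

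The rule for named genes took PEPD, up to 10 called genes per line and direction with the largest fold changes (mean of at least 2 CPM in the higher group, no overlap between the libraries of the groups, an established symbol), up to 4 called members per list and line, up to 10 genes per direction called in both lines, and up to 5 per sign for the difference between lines. It gave 216 genes, of which a part is named. GBP2, BEST1, FTH1, TALAM1, MALAT1, TUBA1B, TUBA1B-AS1, PRKG1-AS1 and MT-ND5 fall outside it and were chosen after their values were seen.

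The alternatives fixed then were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, each line fitted alone, the replicate number as a block, robust estimation off, a test against a log2 fold change of 0.5, and each library left out in turn. Alternatives added after the data were seen were a fit of genes without opposite-strand overlap, a fit without mitochondrially encoded genes, TALAM1, MALAT1 and BEST1, and counts without the interferon list and PEPD. The procedure was tested on simulated data. With counts simulated from these libraries and 200 changed genes, a 4-fold change was called for 93.8% of genes in T98G, 90.5% in U251 and 73.0% for the difference between lines. A 2-fold change was called for 58.7%, 49.2% and 32.8%, and a 1.5-fold change for 17.5%, 35.4% and 7.69%. With no simulated change, the calls numbered 0, 1 and 0. The simulated genes were independent of each other and few were changed, whereas 2837 genes were called in T98G. These rates therefore need not hold for the real data. Replicates within a group differed by more than sampling noise (chi-square per degree of freedom 1.31 to 2.53) and no library held the same counts as another of its group, which does not show whether the replicates were separate cultures. The highest values, 2.10 and 2.53, were those of U251 PEPD-OE replicate 1 against replicates 2 and 3. Between U251 PEPD-OE replicates 2 and 3 the value was 1.41. No sample was left out. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.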

Results

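The series asked how the transcriptome of glioblastoma cells changed when PEPD was over-expressed. PEPD encodes peptidase D, also called prolidase, which splits dipeptides that end in proline or hydroxyproline. T98G and U251 cells, each with 3 PEPD-OE and 3 NC libraries, were profiled by strand-specific sequencing of polyadenylated RNA. The T98G PEPD-OE libraries held 767708, 721782 and 776755 counts, and the T98G NC libraries 464056, 741436 and 763006. The U251 PEPD-OE libraries held 683172, 814220 and 924204 counts, and the U251 NC libraries 874156, 796407 and 840233. Between 14606 and 16862 genes had at least 1 count in a library.

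Many counts stood under genes on the strand opposite an abundant transcript. BEST1, an ion channel gene whose exons overlap FTH1 (ferritin heavy chain), held 486557 counts over the 12 libraries, 5.31% of the total, while FTH1 itself held 10068. TALAM1, the transcript antisense to MALAT1, held 219603 counts against 4272 under MALAT1, and TUBA1B-AS1 held 191395 against 2894 under TUBA1B, a tubulin gene. MT-ND6, which is encoded on the mitochondrial strand opposite most other protein genes, held 233900 counts per kb, against 85224 for MT-ND5, the next highest of the 13 mitochondrially encoded genes, and 10320 for MT-CO1. Among 297 pairs in which at least 95% of a noncoding gene lay inside coding exons of the other strand, and which had at least 100 counts together, the noncoding name had the higher counts per kb in 81.1% (241 pairs, Wilson 95% confidence interval 76.3% to 85.2%). The median log2 ratio of counts per kb, noncoding over coding, was 4.03 (bootstrap 95% interval 3.53 to 4.50). Genes with an opposite-strand overlap held 62.2% to 70.1% of the counts of a library. The nuclear-encoded coding genes with no opposite exon together held 1.76 to 3.19 counts per kb in a library. The noncoding genes inside coding exons held 89.9 to 194. Neither class was filtered by level, and they numbered 13128 and 418 genes. If the reads were counted on the opposite strand, values under genes without overlap, PEPD included, are residual reads and no plain expression levels. Values under the name of a gene with overlap are therefore given with the partner, and calls lost among genes without overlap are named.

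**Figure D1:**
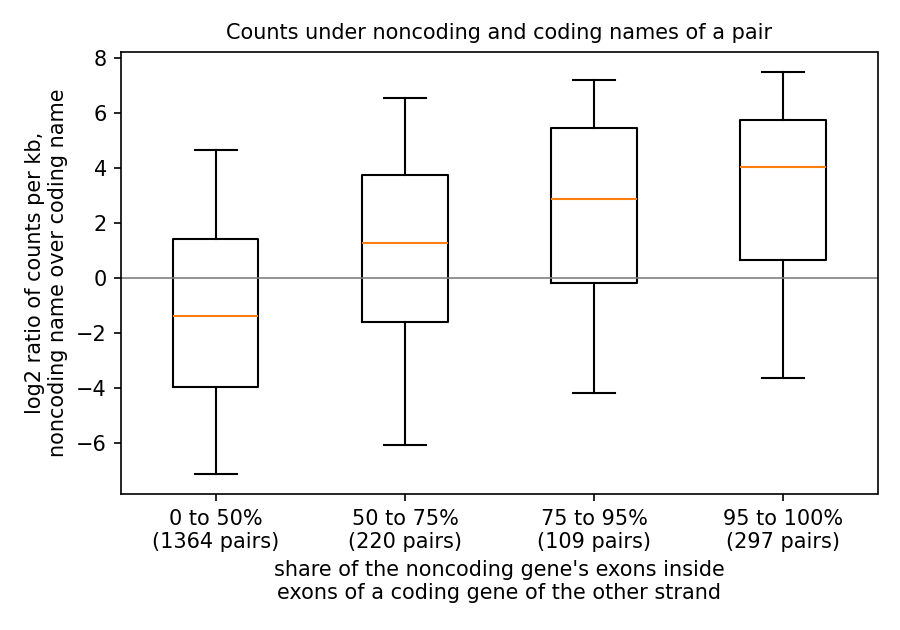
Log2 ratio of counts per kb, noncoding over coding name, for pairs of genes on opposite strands, by the share of the noncoding gene inside coding exons (boxes, median and quartiles; whiskers, 5th to 95th percentile). The median was 4.03 over the 297 pairs with at least 95% inside and -1.38 over the 1364 pairs with less than 50% inside.

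PEPD (ENSG00000124299, GRCh38 chromosome 19, 33386950 to 33521794, minus strand, no exon overlap with the opposite strand) was the first gene examined. In T98G its level was 164 ± 9.50 CPM (SD, n = 3) in PEPD-OE against 19.0, 2.60 and 11.3 CPM in the NC libraries (SD 8.20), a log2 fold change of 4.04 (SE 0.25, edgeR adjusted p = 1.71e-32). In U251 it was 175 ± 10.6 against 9.55 ± 3.44 CPM, a log2 fold change of 4.16 (SE 0.23, adjusted p = 1.86e-35). The lowest PEPD-OE library stood 8.20-fold above the highest NC library in T98G and 12.6-fold above it in U251. The increase did not differ detectably between the lines (difference of log2 fold changes -0.12, adjusted p = 0.886). The NC values rest on few counts, 9, 2 and 9 in the T98G libraries and 11, 5 and 7 in the U251 libraries.

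**Figure D2:**
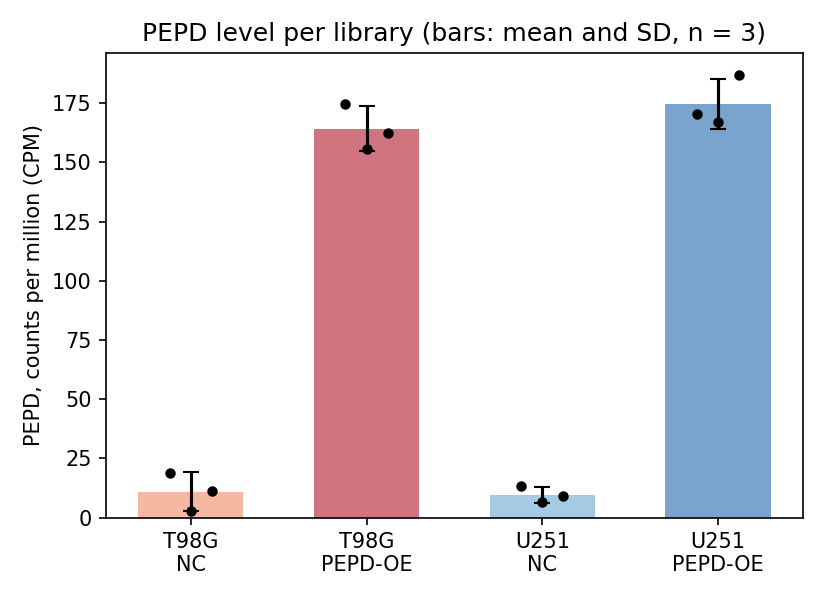
PEPD level in CPM in each of the 12 libraries, with bars at the group mean and the SD of 3 libraries. The 6 PEPD-OE libraries lie between 156 and 187 CPM and the 6 NC libraries between 2.60 and 19.0 CPM.

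In T98G cells, 43 of 47 interferon response genes, 17 of 27 ATF4 and amino acid response genes and 7 of 12 heat shock genes fell under PEPD over-expression, and 23 of 29 NRF2 target and glutathione genes rose. IFI44L, an interferon-induced gene, went from 209 ± 19.6 CPM in NC to 6.95 ± 3.10 CPM in PEPD-OE (n = 3 each, log2 fold change -4.89, SE 0.24). AKR1C2, an aldo-keto reductase under NRF2 control, rose from 91.3 ± 12.3 to 838 ± 51.9 CPM (log2 fold change 3.22, SE 0.14). PSAT1, an enzyme of serine synthesis, fell from 67.2 ± 8.52 to 5.96 ± 2.62 CPM (log2 fold change -3.47, SE 0.34). Among genes in no list, SAT1, which acetylates spermidine and spermine, rose from 16.4 ± 11.1 to 189 ± 21.4 CPM (log2 fold change 3.53, SE 0.23), and counts under CCDC152 (opposite SELENOP, which encodes a selenium transport protein) rose from 74.4 ± 11.2 to 1518 ± 88.0 CPM. SGPP2, a sphingosine-1-phosphate phosphatase, had 3 counts in PEPD-OE against 380 in NC, a 125-fold lower ratio with a counting interval of 42.6 to 611.

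Of 47 measured interferon response genes, 43 fell in T98G, 1 rose and 3 did not pass (44 lower and 1 higher when adjusted over the list alone), and the median log2 fold change was -2.89. MX1 (opposite AP001610.1), a GTPase that restricts viruses, fell from 272 ± 51.7 to 8.50 ± 3.49 CPM (log2 fold change -5.00, SE 0.23). IFI27 had 3 counts in PEPD-OE against 164 in NC, a 54.1-fold lower ratio (18.2 to 265). CMPK2 (opposite RSAD2), a mitochondrial nucleotide kinase induced by interferon, had 0 counts against 28 and was at least 9.24-fold lower. GBP2, an interferon-induced GTPase, rose (log2 fold change 1.29, SE 0.20). The list was called lower by camera (adjusted p = 3.49e-48, and adjusted p = 7.58e-04 with an estimated correlation), and also among its 32 members without opposite-strand overlap, of which 27 fell (adjusted p = 5.78e-38). Antigen presentation genes had a lower median of -0.71, with 7 of 16 lower and 1 higher (9 and 1 when adjusted over the list alone). Of them, TAP1 (opposite PSMB8-AS1), a peptide transporter also in the interferon list, fell by 2.08 on the log2 scale (SE 0.37). That list's call (adjusted p = 0.0356) was lost with an estimated correlation (adjusted p = 0.308), without T98G NC replicate 2 (adjusted p = 0.0522), with each line fitted alone (adjusted p = 0.0568) and among genes without opposite-strand overlap (adjusted p = 0.209).

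**Figure D3:**
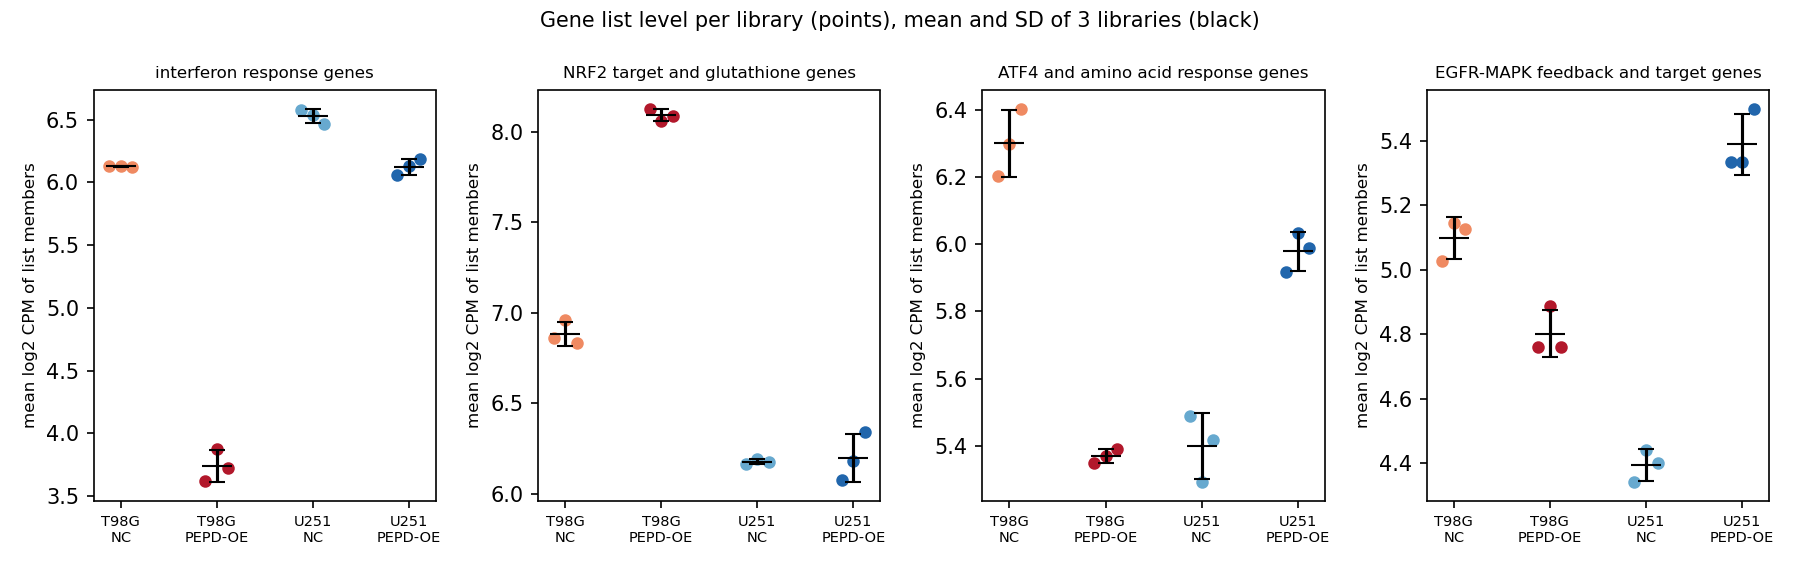
Mean log2 CPM of the measured members of 4 gene lists in each library, with the group mean and SD of 3 libraries. The interferon response list lies near 6.13 in the T98G NC libraries and between 3.62 and 3.87 in the T98G PEPD-OE libraries, and in U251 between 6.47 and 6.58 in NC and between 6.06 and 6.19 in PEPD-OE.

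Of 29 measured NRF2 target and glutathione genes, 23 rose in T98G and 6 did not pass (24 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.15. AKR1B10, another aldo-keto reductase, rose from 50.4 ± 3.54 to 398 ± 12.1 CPM (log2 fold change 2.96, SE 0.16), and OSGIN1, an oxidative stress response gene, rose from 17.7 ± 3.68 to 129 ± 4.84 CPM (log2 fold change 2.90, SE 0.24). By camera the list was higher (adjusted p = 9.71e-24, and adjusted p = 0.00419 with an estimated correlation). Fatty acid synthesis and desaturation genes were also called higher, with 6 of 16 up and none down, both over all genes and adjusted over the list alone, and a median of 0.40. Of these, the desaturase SCD rose from 47.8 ± 3.20 to 177 ± 6.79 CPM (log2 fold change 1.88, SE 0.18) and the desaturase FADS2 (opposite FADS1) rose by 2.13 on the log2 scale (SE 0.27). The call (adjusted p = 0.0108) was lost with an estimated correlation (adjusted p = 0.0642) and among genes without opposite-strand overlap (adjusted p = 0.0563). Cholesterol biosynthesis genes were not called (6 higher and 1 lower of 13, median 0.56, adjusted p = 0.194).

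Of 27 measured ATF4 and amino acid response genes, 17 fell, 2 rose and 8 did not pass (21 lower and 2 higher when adjusted over the list alone), with a median of -0.91. STC2, a secreted glycoprotein induced by stress, fell by 2.46 on the log2 scale (SE 0.16, n = 3), and SLC7A5 (opposite AC126696.2), a carrier of large neutral amino acids, fell from 267 ± 30.1 to 75.2 ± 7.30 CPM (log2 fold change -1.83, SE 0.15). The transcription factor CEBPB (opposite CEBPB-AS1) and the amino acid carrier SLC38A2 rose by 1.45 (SE 0.16) and 0.52 (SE 0.15) on the log2 scale. Camera called it lower (adjusted p = 5.50e-09, and adjusted p = 0.0158 with an estimated correlation). Of 12 heat shock genes, 7 fell and none rose (8 lower when adjusted over the list alone), with a median of -0.95. The chaperone genes DNAJA1 and HSPA8 fell from 279 ± 1.32 to 74.0 ± 11.1 CPM and from 801 ± 60.1 to 329 ± 47.4 CPM. This list was called lower as well (adjusted p = 1.05e-07, and adjusted p = 0.0237 with an estimated correlation). Endoplasmic reticulum chaperones and unfolded protein response genes were not called (0 higher and 8 lower of 23, median -0.22, adjusted p = 0.0786).

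Of 33 measured G1/S genes, 13 fell and none rose in T98G, with a median of -0.47. UHRF1, which maintains DNA methylation at replication, fell from 160 ± 24.8 to 54.0 ± 10.9 CPM (log2 fold change -1.54, SE 0.18). The call (adjusted p = 0.00156) was lost with an estimated correlation (adjusted p = 0.0642). G2/M genes were not called (3 higher and 6 lower of 45, 3 and 2 over the list alone, median -0.00, adjusted p = 0.874).

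In T98G, COL1A2, a chain of type I collagen, rose from 224 ± 33.9 to 534 ± 73.1 CPM (log2 fold change 1.25, SE 0.12), and LOX (opposite SRFBP1), a collagen crosslinking enzyme, rose from 142 ± 11.7 to 320 ± 8.28 CPM (log2 fold change 1.17, SE 0.14). Of 23 collagen modification and crosslinking genes, 11 rose and none fell, with a median of 0.44. That call (adjusted p = 0.0482) was lost with an estimated correlation (adjusted p = 0.238), under upper-quartile scaling (adjusted p = 0.0624), with each line fitted alone (adjusted p = 0.0582), with robust estimation off (adjusted p = 0.0696), without T98G PEPD-OE replicate 3 (adjusted p = 0.0709), without T98G NC replicate 2 (adjusted p = 0.0522), without the mitochondrial genes, TALAM1, MALAT1 and BEST1 (adjusted p = 0.0522) and among genes without opposite-strand overlap (adjusted p = 0.391). The collagens were not called (9 higher and 4 lower of 21, median 0.51, or 0.53 with genes that had a group at 0 counts placed at their bound, adjusted p = 0.164). Among 15 proline metabolism and peptidase genes, 4 rose and 1 fell, with a median of 0.02, a mean of 0.04 and a test in the downward direction (adjusted p = 0.940). PYCR1 (opposite AC145207.4), which makes proline, had a log2 fold change of 0.97 (SE 0.28, adjusted p = 0.00311), a call lost without T98G NC replicate 2 (adjusted p = 0.104).

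The share of counts under the 13 mitochondrially encoded genes was 9.73%, 7.95% and 8.63% in the T98G PEPD-OE libraries against 6.14%, 5.94% and 5.07% in NC. The share under TALAM1 was 4.18%, 3.54% and 3.48% against 1.23%, 1.11% and 1.20%. Of the 13 mitochondrially encoded genes, 9 rose and none fell (median 0.61). MT-ND6 rose by 1.13 on the log2 scale (SE 0.08). The list was called higher (adjusted p = 3.26e-05), a call lost with an estimated correlation (adjusted p = 0.350). Nuclear-encoded oxidative phosphorylation genes were not called (1 higher and 1 lower of 39, 0 and 1 over the list alone, median -0.08, adjusted p = 0.681), nor were cytosolic ribosomal protein genes (2 higher and 3 lower of 65, 1 and 0 over the list alone, median 0.04, test downward, adjusted p = 0.940).

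No other tested list was called in T98G. Hypoxia response genes were 12 higher and 2 lower of 28 (13 and 2 over the list alone, median 0.50, adjusted p = 0.130). Of these CA12, a carbonic anhydrase, rose from 36.1 ± 6.97 to 204 ± 1.30 CPM. Glycolysis genes were 8 higher and 1 lower of 20 (median 0.16, adjusted p = 0.234), and autophagy and lysosome genes 6 higher and 1 lower of 29 (median 0.24, adjusted p = 0.234). EGFR-MAPK feedback and target genes were 1 higher and 7 lower of 17 (median -0.46, adjusted p = 0.0786), YAP-TEAD target genes 4 higher and 5 lower of 20 (4 and 6 over the list alone, median -0.36, or -0.35 with genes that had a group at 0 counts placed at their bound, adjusted p = 0.194), and immediate early genes 3 higher and none lower of 9 (3 and 1 over the list alone, median 0.26, adjusted p = 0.294). TGF-beta target genes were 7 higher and 3 lower of 23 (7 and 4 over the list alone, median 0.19, adjusted p = 0.400), angiogenic factors 6 higher and 2 lower of 16 (6 and 3 over the list alone, median 0.06, adjusted p = 0.940), and integrins 2 higher and 2 lower of 13 (median 0.02, test downward, adjusted p = 0.940). Mesenchymal transition genes were 7 higher and 5 lower of 16 (median -0.23, adjusted p = 0.940), and extracellular matrix glycoproteins and proteoglycans 6 higher and 6 lower of 29 (8 and 6 over the list alone, median 0.40, or 0.31 at the bounds, adjusted p = 0.910).

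The median, mean and test of several lists differed in sign in T98G. Extracellular matrix proteases and inhibitors were 7 higher and 7 lower of 22 (median 0.33, mean -0.03, test upward, adjusted p = 0.874). The p53 target genes were 3 higher and 4 lower of 17 (median 0.26, mean -0.09, test upward, adjusted p = 0.940). Inflammatory and NF-kB target genes were 1 higher and 3 lower of 13 (median 0.24, mean -0.13, test downward, adjusted p = 0.940). Genes of the mesenchymal-like glioblastoma state were 6 higher and 4 lower of 21 (8 and 5 over the list alone, median -0.12, mean 0.11, test upward, adjusted p = 0.681), and those of the astrocyte-like state 1 higher and 1 lower of 8 (median 0.01, or 0.21 at the bounds, mean -0.14, test upward, adjusted p = 0.676). Genes of the oligodendrocyte- and neural-progenitor-like states were 1 higher and none lower of 5 (median 0.29, adjusted p = 0.796), and neural and glioma stem genes 0 higher and 2 lower of 9 (median -0.15, or -0.51 at the bounds, adjusted p = 0.245). Of the markers of other cells, 4 epithelial genes were measured, among which CLDN4, a tight junction gene, rose by 2.13 on the log2 scale (SE 0.23) and KRT8 (opposite KRT18) fell by 0.80 (SE 0.22), a call lost without T98G PEPD-OE replicate 1 (adjusted p = 0.105). Of 4 fibroblast markers, COL1A2 rose, and PDGFRB rose by 0.59 on the log2 scale (SE 0.22, adjusted p = 0.0278), a call lost in 7 settings (adjusted p = 0.0554 to 0.137). No marker of macrophages and microglia or of endothelium passed the filter, and of the replication-dependent histones 2 did, neither of them called in either line.

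Of the 8773 genes tested, 2837 were called in T98G, 1551 higher and 1286 lower, and 1443 of them changed at least 2-fold (838 higher and 605 lower). Without adjustment, 3587 genes had a p under 0.05. In 43.5% of the genes tested, all 3 T98G PEPD-OE libraries lay on one side of all 3 NC libraries, where chance gives 10%. Of the 9 lists called, 4 held with an estimated correlation. Among genes without opposite-strand overlap, 1173 were called.

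In U251 cells, 13 of 17 EGFR-MAPK feedback and target genes, 7 of 20 YAP-TEAD target genes, 10 of 27 ATF4 and amino acid response genes and 8 of 33 G1/S genes rose under PEPD over-expression, and 21 of 47 interferon response genes fell. CCN2 (opposite AL133346.1), a matrix-associated growth factor and YAP target, rose from 99.7 ± 10.8 CPM in NC to 492 ± 49.2 CPM in PEPD-OE (n = 3 each, log2 fold change 2.30, SE 0.13). CCND1 (opposite LTO1), the G1 cyclin D1, rose from 71.0 ± 9.04 to 229 ± 18.5 CPM (log2 fold change 1.68, SE 0.15). LIF (opposite AC004264.1), a cytokine of the IL6 family, rose from 3.34 ± 1.93 to 25.1 ± 2.26 CPM, and IGFBP3, which binds insulin-like growth factors, from 2.95 ± 3.25 to 18.4 ± 0.569 CPM. KRT15, an epithelial keratin, fell from 70.6 ± 11.5 to 8.61 ± 3.70 CPM (log2 fold change -2.95, SE 0.30). Counts under CCDC152 (opposite SELENOP) fell from 259 ± 8.36 to 78.2 ± 11.4 CPM, and N4BP2 (opposite AC098591.1) fell by 2.02 on the log2 scale (SE 0.42).

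Of 17 measured EGFR-MAPK feedback and target genes, 13 rose in U251 and none fell, with a median log2 fold change of 1.21. The transcription factor gene EGR1 rose from 8.83 ± 2.35 to 42.6 ± 0.401 CPM (log2 fold change 2.26, SE 0.33), and FOSL1, a subunit of AP-1, rose from 34.2 ± 4.80 to 103 ± 15.0 CPM (log2 fold change 1.60, SE 0.20). ETV4 (opposite DHX8), a transcription factor downstream of ERK, had 32 counts in PEPD-OE against 1 in NC, a 31.3-fold higher ratio with a counting interval of 5.24 to 1276. By camera these genes were higher as a list (adjusted p = 2.36e-16, and adjusted p = 0.00168 with an estimated correlation). Of 9 immediate early genes, 5 rose (6 when adjusted over the list alone) and none fell, with a median of 0.73 (adjusted p = 5.67e-08, and adjusted p = 0.00222 with an estimated correlation). Among those that rose, FOS, EGR1 and MYC are also in the EGFR-MAPK list, and CCN1 is also in the YAP-TEAD and angiogenic lists. The calls of these lists are therefore not independent. Of 20 YAP-TEAD target genes, 7 rose (8 when adjusted over the list alone) and none fell, with a median of 0.55 (adjusted p = 2.23e-09, and adjusted p = 0.00168 with an estimated correlation). NT5E, an ectonucleotidase on that list, rose from 48.9 ± 21.6 to 99.6 ± 7.81 CPM. Of 16 angiogenic factors, 4 rose (5 when adjusted over the list alone), with a median of 0.27 (adjusted p = 3.47e-04, and adjusted p = 0.0140 with an estimated correlation). THBS1 (opposite FSIP1), a matrix protein on that list that inhibits angiogenesis, rose from 306 ± 51.4 to 675 ± 78.3 CPM.

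Of 27 ATF4 and amino acid response genes, 10 rose in U251 and none fell (16 higher and 1 lower when adjusted over the list alone), with a median of 0.58. SLC7A5 rose from 28.3 ± 9.28 to 87.4 ± 5.43 CPM (log2 fold change 1.61, SE 0.21), STC2 from 14.2 ± 3.43 to 41.8 ± 4.39 CPM (log2 fold change 1.53, SE 0.28) and TRIB3, a pseudokinase induced by ATF4, from 6.23 ± 1.90 to 22.4 ± 8.26 CPM (log2 fold change 1.86, SE 0.41). The list was called higher (adjusted p = 6.02e-12, and adjusted p = 0.00168 with an estimated correlation). Of 33 G1/S genes, 8 rose and none fell (13 higher when adjusted over the list alone), with a median of 0.54 (adjusted p = 1.68e-07, and adjusted p = 0.00659 with an estimated correlation). CLSPN (opposite AL354864.1), a replication checkpoint gene, rose from 38.9 ± 5.94 to 76.1 ± 18.9 CPM (log2 fold change 0.97, SE 0.20). The p53 target genes were called higher with 2 of 17 up (3 when adjusted over the list alone) and a median of 0.35 (adjusted p = 0.00148), a call lost with an estimated correlation (adjusted p = 0.0530), without a filter (adjusted p = 0.121) and with at least 1 CPM in at least 3 libraries (adjusted p = 0.117). Its 2 members called were the growth factor GDF15 (log2 fold change 1.78, SE 0.23) and the growth arrest gene GADD45A (1.43, SE 0.21). Cholesterol biosynthesis genes were called higher with 3 of 13 up (4 when adjusted over the list alone) and a median of 0.55 (adjusted p = 0.00143), a call lost with an estimated correlation (adjusted p = 0.0808) and without U251 PEPD-OE replicate 2 (adjusted p = 0.0554). One of the 3 was HMGCS1 (opposite AC114947.2), which makes the precursor of mevalonate (log2 fold change 0.86, SE 0.27, adjusted p = 0.0314). Its call was lost under DESeq2, without a filter, and without U251 PEPD-OE replicates 1 or 2 or U251 NC replicates 2 or 3 (adjusted p up to 0.315). The cholesterol list could not be tested among genes without opposite-strand overlap, as 4 members remained, fewer than the 5 required.

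Of the 47 interferon response genes, 21 fell in U251 and none rose (28 lower when adjusted over the list alone), with a median of -0.45, or -0.44 with genes that had a group at 0 counts placed at their bound. ISG15 (opposite AL645608.3), a ubiquitin-like modifier, fell from 950 ± 88.7 to 525 ± 108 CPM (log2 fold change -0.85, SE 0.10), IFIT1, which binds viral RNA, from 298 ± 42.3 to 159 ± 38.2 CPM (-0.89, SE 0.13) and IFI27 from 409 ± 40.7 to 242 ± 74.7 CPM (-0.74, SE 0.13). The list was called lower (adjusted p = 1.99e-15, and adjusted p = 0.00168 with an estimated correlation), and among its 32 members without opposite-strand overlap 13 fell (adjusted p = 1.54e-13). Antigen presentation genes were 0 higher and 0 lower of 16 (median -0.17, or -0.18 at the bounds, adjusted p = 0.156).

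Of the 13 mitochondrially encoded genes, 5 fell and none rose in U251 (median -0.32, adjusted p = 1.41e-05), a call lost with an estimated correlation (adjusted p = 0.304). Fry, which asks another question, did not call the list (adjusted p = 0.0580). MT-ND6 fell by 0.63 on the log2 scale (SE 0.08). The mitochondrial share of counts was 5.30%, 3.63% and 3.57% in PEPD-OE against 5.34%, 4.50% and 4.92% in NC, and the TALAM1 share 2.30%, 1.75% and 1.78% against 2.63%, 2.31% and 2.87%. Nuclear-encoded oxidative phosphorylation genes were called lower with 2 of 39 down (1 when adjusted over the list alone) and a median of -0.30 (adjusted p = 0.00143), a call lost with an estimated correlation (adjusted p = 0.241) and without U251 PEPD-OE replicate 1 (adjusted p = 0.0800). One of the 2 was UQCRB (opposite AP003465.1), a subunit of complex III (log2 fold change -0.79, SE 0.20), whose call was lost without U251 NC replicate 1 (adjusted p = 0.0503). Glycolysis genes were called lower with 4 of 20 down and a median of -0.11 (adjusted p = 0.0377), a call lost with an estimated correlation (adjusted p = 0.304), without U251 PEPD-OE replicate 1 (adjusted p = 0.211), without U251 NC replicate 2 (adjusted p = 0.125) and among genes without opposite-strand overlap (adjusted p = 0.624). Fry did not call the glycolysis list either (adjusted p = 0.0528). GAPDH (opposite AC006064.4), a glycolytic enzyme, fell by 0.69 on the log2 scale (SE 0.08).

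No other tested list was called in U251. Heat shock genes were 4 higher and 1 lower of 12 (median 0.02, adjusted p = 0.156), with HSP90AA1 (opposite WDR20), a cytosolic chaperone, up from 518 ± 48.1 to 886 ± 57.6 CPM. Endoplasmic reticulum chaperones and unfolded protein response genes were 2 higher and 1 lower of 23 (median 0.04, adjusted p = 0.262). NRF2 target and glutathione genes were 3 higher and 5 lower of 29 (median -0.01, mean 0.07, test downward, adjusted p = 0.990), fatty acid genes 1 higher and none lower of 16 (median 0.19, adjusted p = 0.270), and G2/M genes 0 higher and 0 lower of 45 (median 0.08, adjusted p = 0.132). Hypoxia response genes were 3 higher and none lower of 28 (5 and 1 over the list alone, median 0.08, adjusted p = 0.485), autophagy and lysosome genes 1 higher and 2 lower of 29 (median -0.12, adjusted p = 0.156), and ribosomal protein genes 0 higher and 2 lower of 65 (median -0.03, adjusted p = 0.181). Collagens were 2 higher and 1 lower of 21 (2 and 2 over the list alone, median -0.26, adjusted p = 0.366), with COL1A2 lower, from 507 ± 23.1 to 346 ± 44.5 CPM, and collagen modification genes 0 higher and 0 lower of 23 (median -0.25, adjusted p = 0.103). Proline metabolism and peptidase genes were 1 higher and 1 lower of 15 (median -0.10, adjusted p = 0.860), and integrins 1 higher and 1 lower of 13 (median 0.07, adjusted p = 0.643). Extracellular matrix glycoproteins and proteoglycans were 2 higher and 3 lower of 29 (3 and 5 over the list alone, median -0.06, adjusted p = 0.842).

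Other lists whose median, mean or test differed in sign in U251 were extracellular matrix proteases and inhibitors (1 higher and 2 lower of 22, 3 and 2 over the list alone, median -0.03, or -0.06 at the bounds, mean 0.01, test downward, adjusted p = 0.947), TGF-beta target genes (4 higher and 3 lower of 23, 4 and 4 over the list alone, median -0.06, or -0.08 at the bounds, mean 0.14, test upward, adjusted p = 0.181), mesenchymal transition genes (3 higher and 3 lower of 16, median -0.04, mean 0.09, test upward, adjusted p = 0.710) and inflammatory and NF-kB target genes (2 higher and none lower of 13, median -0.01, mean 0.25, test upward, adjusted p = 0.485). Genes of the mesenchymal-like state were 1 higher and 2 lower of 21 (median -0.06, adjusted p = 0.803), and those of the astrocyte-like state 0 higher and 1 lower of 8 (0 and 2 over the list alone, median -0.19, adjusted p = 0.156). The one called was GFAP (opposite CCDC103), the astrocyte intermediate filament, which fell from 1436 ± 83.5 to 930 ± 64.7 CPM. Genes of the oligodendrocyte- and neural-progenitor-like states were 0 higher and 0 lower of 5 (0 and 1 over the list alone, median -0.23, or -0.26 at the bounds, adjusted p = 0.181), and neural and glioma stem genes 1 higher and 1 lower of 9 (1 and 2 over the list alone, median -0.09, or -0.07 at the bounds, adjusted p = 0.643). Of the 4 epithelial markers KRT15 was called, and of the 4 fibroblast markers COL1A2.

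Of the 8773 genes tested, 750 were called in U251, 362 higher and 388 lower, and 183 of them changed at least 2-fold (111 higher and 72 lower). Without adjustment, 1794 genes had a p under 0.05. All 3 U251 PEPD-OE libraries lay on one side of all 3 NC libraries in 22.4% of the genes tested, where chance gives 10%. Of the 12 lists called, 7 held with an estimated correlation. The number of genes called fell to 440 without U251 PEPD-OE replicate 2, 449 without U251 NC replicate 1, 442 without U251 NC replicate 3 and 415 under DESeq2. Among genes without opposite-strand overlap, 278 were called.

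**Figure D4:**
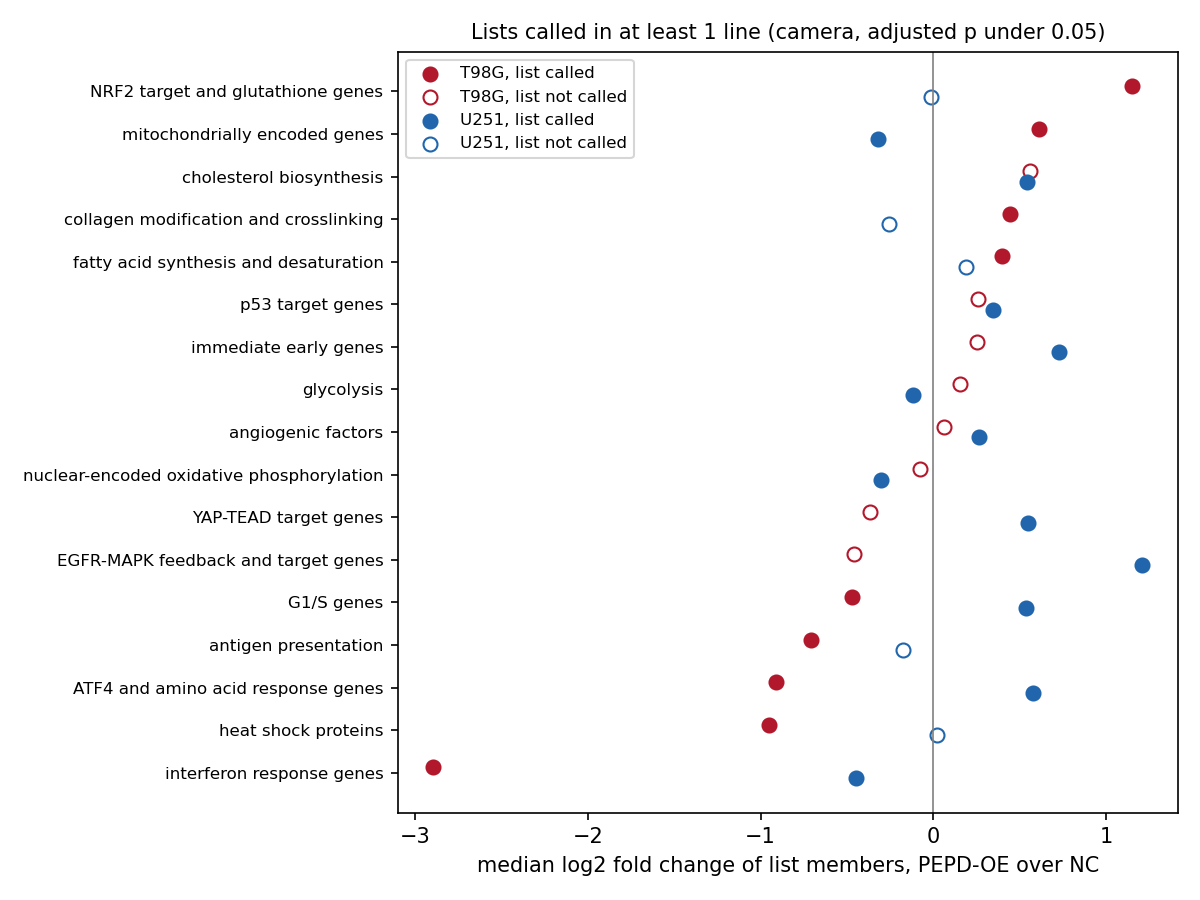
Median log2 fold change (PEPD-OE over NC) of the 17 gene lists called in at least 1 line, T98G in red and U251 in blue, open symbols where the list was not called. The interferon response list is below 0 in both lines (-2.89 and -0.45), while the ATF4 list is -0.91 in T98G and 0.58 in U251.

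The lines were then compared by testing the difference between their changes. The interferon response genes fell further in T98G than in U251 (median difference -2.63, 35 of 47 members lower and 1 higher in T98G relative to U251), and the ATF4 list (-1.41, 22 of 27 lower, 1 higher) and the EGFR-MAPK list (-1.39, 12 of 17 lower) were also lower in T98G relative to U251. The NRF2 list was higher (0.99, 18 of 29 higher, 1 lower). SLC7A5 fell by 1.83 on the log2 scale in T98G and rose by 1.61 in U251 (difference -3.44, adjusted p = 1.84e-25). THBS1 fell by 2.21 and rose by 1.14 (difference -3.36, adjusted p = 1.08e-46), and FOSL1 fell by 1.45 and rose by 1.60 (difference -3.05, adjusted p = 5.57e-21). COL1A2 went the other way, up by 1.25 in T98G and down by 0.55 in U251 (difference 1.80, adjusted p = 1.59e-19).

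In all, 10 lists differed between the lines by camera: the interferon (adjusted p = 3.79e-27, and 0.00401 with an estimated correlation), ATF4 (1.00e-14, and 0.00463), NRF2 (1.87e-09, and 0.0173), EGFR-MAPK (2.76e-07, and 0.0173), heat shock (median difference -1.04, 7 of 12 lower and 1 higher, adjusted p = 2.76e-07, and 0.0173), G1/S (-0.94, 16 of 33 lower, 7.01e-07, and 0.0173) and YAP-TEAD lists (-1.30, 8 of 20 lower and 2 higher, 5.22e-04, and 0.0173) held their call with an estimated correlation. The mitochondrially encoded genes (1.01, 9 of 13 higher, adjusted p = 2.58e-08), collagen modification genes (0.62, 10 of 23 higher and 1 lower, adjusted p = 0.0174) and glycolysis genes (0.35, 9 of 20 higher and 1 lower, adjusted p = 0.0494) lost theirs (adjusted p = 0.213, 0.114 and 0.366 with an estimated correlation). Among genes without opposite-strand overlap the collagen modification list (adjusted p = 0.114) and the glycolysis list (adjusted p = 0.106) were not called, and the glycolysis call was also lost under upper-quartile scaling (adjusted p = 0.0572), with robust estimation off (adjusted p = 0.0605), and without T98G PEPD-OE replicates 2 or 3, T98G NC replicate 1, U251 PEPD-OE replicate 1 or U251 NC replicate 2 (adjusted p up to 0.112).

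Genes called in both lines moved in opposite directions more often than in the same one. Of 438 such genes, 349 moved in opposite directions and 89 in the same direction (20.3%). Higher in T98G and lower in U251 were 183 genes (68.6 expected for independent lists, one-sided Fisher's exact test, adjusted p = 2.14e-42), and lower in T98G and higher in U251 were 166 (53.1 expected, adjusted p = 2.11e-47). Higher in both were 38 (64.0 expected, adjusted p = 1.00) and lower in both 51 (56.9 expected, adjusted p = 1.00). The lines share no control libraries. The opposite overlaps also exceeded expectation among genes without opposite-strand overlap (45 against 17.9, adjusted p = 1.05e-09, and 72 against 21.4, adjusted p = 2.74e-23). Across the 8773 genes, the log2 fold changes of the lines had a Pearson correlation of -0.205 and a Spearman correlation of -0.240. The counts of shared genes rest on the U251 calls and fell to 56 the same way and 218 the opposite way without U251 PEPD-OE replicate 2, to 56 and 222 without U251 NC replicate 1, to 59 and 201 without U251 NC replicate 3, to 53 and 218 under DESeq2 and to 51 and 227 without a filter.

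**Figure D5:**
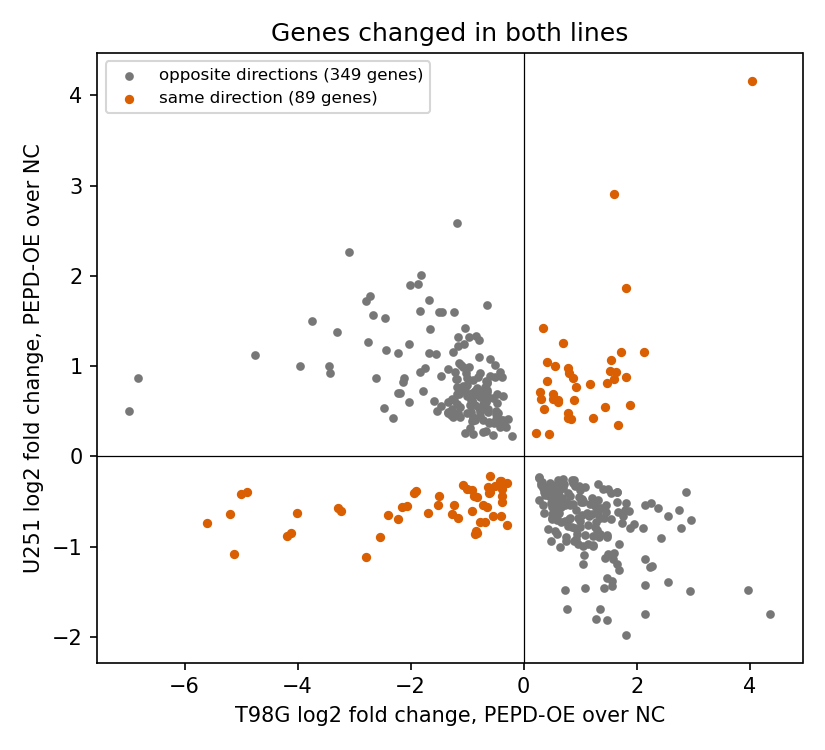
Log2 fold change in U251 against that in T98G for the 438 genes called in both lines. The 349 genes with opposite signs are grey and the 89 genes with the same sign are orange.

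Genes that fell in both lines included several of the interferon list. ISG15 had log2 fold changes of -4.11 in T98G and -0.85 in U251, IFIT1 of -2.54 and -0.89, and IFIT2 (opposite LIPA) of -4.19 and -0.88. HELZ2, a transcriptional coactivator, fell by 2.22 and 0.70, and ACO1, the cytosolic aconitase that also binds iron-responsive elements, by 0.77 and 0.73 on the log2 scale. Besides PEPD, EGLN1, the oxygen-sensing prolyl hydroxylase, rose in both lines (1.81, SE 0.49, adjusted p = 0.00170 in T98G, and 1.86, SE 0.50, adjusted p = 0.00732 in U251), as did TXNRD1, a thioredoxin reductase (0.94 and 0.77), and JUN, a subunit of AP-1 (0.90 and 0.63). Without the interferon list and PEPD, 31 genes were lower in both lines, against 52.3 expected.

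Over all genes, 2428 differed between the lines in their change, 1239 higher and 1189 lower in T98G relative to U251, and 1749 of them by at least 2-fold (912 and 837). Without adjustment, 3264 genes had a p under 0.05, and 972 of the genes without opposite-strand overlap were called. Of the 4 lists called in both lines, the interferon list was called in the same direction, and the ATF4, G1/S and mitochondrially encoded lists in opposite directions. With an estimated correlation the calls of the G1/S list in T98G (adjusted p = 0.0642) and of the mitochondrially encoded list in T98G (adjusted p = 0.350) and U251 (adjusted p = 0.304) were lost, which leaves the ATF4 list of the 3.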

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

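The explanations of the strand counts, of the interferon decrease and of the opposite directions were tested with several rules set only after the result was seen: opposite-strand counting, counting without regard to strand, partner reads and single libraries for the interferon list, the state of the NC cells, swapped labels and the culture state. The rules for antisense transcription, gene length and GC content, and random splits of the libraries were set before their results.

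Counts stood under noncoding names inside coding exons of the other strand. In 81.1% of 297 pairs the noncoding name held the higher counts per kb, which is what counting stranded reads on the wrong strand would give. Counting without regard to strand would put the median log2 ratio at or under 0, and it was 4.03. Antisense transcription above that of coding genes cannot be told apart from wrong-strand counting. The noncoding genes held at least 47.4 times the counts per kb of nuclear-encoded coding genes with no opposite exon in every library. Such transcription would raise this ratio too, so the rule set for it, that a high ratio excludes it, was wrong. The strand setting of the counting is not given in the sources used here, and the reads were not analysed here.

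The interferon response list was called lower in both lines. Reads of opposite-strand partners may have made the decrease, but the list stayed lower in both lines among genes without such overlap (higher of the adjusted p values 1.54e-13). It also stayed lower with each library left out (highest adjusted p = 3.99e-13, without U251 PEPD-OE replicate 1), which excludes a single library as its source. Whether PEPD-OE cells lost interferon signalling or NC cells gained it cannot be told apart, as 0 libraries stood outside the PEPD-OE and NC groups and the labels do not say what NC cells carried.

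Genes called in both lines moved mostly in opposite directions. Labels swapped in one line could give this, but the lowest PEPD-OE library stood at least 8.20-fold above the highest NC library for PEPD in each line. Bias by gene length and GC content could also give it, but a smooth trend over both explained 0.797% of the variance of the log2 fold changes in T98G and 1.74% in U251, and taking it out moved the Spearman correlation between the lines from -0.239 to -0.236 (bootstrap 95% interval -0.258 to -0.215). Length and GC were those of the longest transcript of the named gene. For the 4489 genes with opposite-strand overlap, counts may be reads of the partner, so these values may belong to the wrong transcript. The trend does not decide the question for those genes. A difference in culture state at harvest might act as well, and 3 lists were called in opposite directions in the lines (ATF4, G1/S and mitochondrially encoded genes). With an estimated correlation the G1/S call in T98G (adjusted p = 0.0642) and the mitochondrial calls in T98G (adjusted p = 0.350) and U251 (adjusted p = 0.304) were lost, which leaves ATF4. Culture conditions are not given in the sources used here, so this cannot be told apart from a response that depends on the line. The composition of the libraries also moved in opposite ways. The 5 genes with most counts in a library held 15.8% to 16.9% in T98G PEPD-OE against 10.5% to 11.6% in NC. In U251 they held 11.4% to 12.2% against 13.2% to 14.2%. Whether this is a source or a part of the opposite changes cannot be told apart.

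Random regrouping of the libraries could give calls by chance. Within a line only 10 splits exist, too few for a share under 0.05: the real split was the 1 of 10 with as many genes in T98G (2837, highest other 0) and in U251 (750, highest other 2), and the 1 of 10 with as many lists in T98G (9, highest other 8) and in U251 (12, highest other 7). For the difference between lines, 1 of 100 joint splits, the real one, gave as many genes (2428, highest other 1527), but 9 of 100 gave as many lists (10, highest other 13), so chance is not excluded for the number of lists that differed. The 8 other splits with as many all kept the U251 groups, as labelled or reversed, and so hold the U251 change itself, while splits that mixed the groups of both lines gave at most 8 lists. Nor do the splits decide the number of genes that differed. A line with mixed groups adds its own change to the spread that all groups share in the fit. With only T98G mixed, U251 with its groups kept called 19 to 26 genes instead of 750, and 1 to 4 genes differed between the lines. For genes changed the same way (89, highest other 0) and in opposite directions (349, highest other 0), 1 of 100 splits, the real one, gave as many. A gene must be called in both lines to enter these counts. A line with mixed groups called 0 genes in T98G and at most 2 in U251, so the other splits had no shared genes whatever the direction. The 100 were drawn from 200, without the split that reversed U251 alone, which would exchange the 2 counts. The splits therefore do not test the direction of shared genes.

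A difference between the lines singled out 2428 genes and the following results. The median differences of the lists were -2.63 for interferon response genes, -1.41 for ATF4 and amino acid response genes, -1.39 for EGFR-MAPK targets, -1.30 for YAP-TEAD targets, -1.04 for heat shock proteins, -0.94 for G1/S genes, 0.35 for glycolysis, 0.62 for collagen modification, 0.99 for NRF2 targets and 1.01 for mitochondrially encoded genes. With an estimated correlation the calls of the glycolysis (adjusted p = 0.366), collagen modification (adjusted p = 0.114) and mitochondrially encoded lists (adjusted p = 0.213) were lost. Among called genes with a mean of at least 2 CPM in the highest group and an established symbol, the 5 most positive and the 5 most negative fitted differences of log2 fold changes were those of CCDC152 (opposite SELENOP, 6.11), RCN3 (5.77), SLC25A27 (5.66), CFI (5.45) and SPAG4 (4.78) on the higher side, and SGPP2 (-7.69), CMPK2 (opposite RSAD2, -6.04), USP18 (-5.36), KRT80 (-5.35) and GFRA1 (-5.25) on the lower side. RCN3, SLC25A27, CFI and CMPK2 had a group at 0 counts, so these fitted values and their order are no bounds. CFI had 5 counts against 0 in T98G, a bound of 1.68-fold whose counting interval starts at 0.926. In T98G, the PEPD-OE and NC groups had 1 and 29 counts for USP18, a 28.7-fold lower ratio (counting interval 4.76 to 1172), 2 and 73 for KRT80, 36.1-fold lower (9.65 to 304), and 1 and 18 for GFRA1, 17.8-fold lower (2.81 to 742). The call was lost for RCN3 without U251 NC replicate 1 (adjusted p = 0.178), for SLC25A27 without U251 NC replicate 2 (adjusted p = 0.0625) and for CFI without T98G PEPD-OE replicate 2 (adjusted p = 0.0636).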

How the results depend on the processing

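The T98G gene count (2837) was 1385 in a test against a log2 fold change of 0.5 and 1140 in a fit of genes without opposite-strand overlap. The U251 count (750) was 415 under DESeq2, 76 against a log2 fold change of 0.5 and 245 without overlap genes. Its balance of 362 higher and 388 lower was 158 and 257 under DESeq2, 49 and 27 against a log2 fold change of 0.5, 134 and 111 without overlap genes, and 312 and 457 without the mitochondrial genes, TALAM1, MALAT1 and BEST1. With each library left out it ranged from 440 to 742, falling to 440 without U251 PEPD-OE replicate 2, 449 without U251 NC replicate 1 and 442 without U251 NC replicate 3. The 2428 genes whose change differed between the lines became 1473 against a log2 fold change of 0.5 and 917 without overlap genes. The 89 genes changed the same way became 53 under DESeq2, 51 without a filter, 6 against a log2 fold change of 0.5 and 30 without overlap genes, and ranged from 56 to 85 with each library left out (56 without U251 PEPD-OE replicate 2, 56 without U251 NC replicate 1, 59 without U251 NC replicate 3). The 349 genes changed in opposite directions became 218 under DESeq2, 227 without a filter, 32 against a log2 fold change of 0.5 and 103 without overlap genes, and ranged from 201 to 341 (218, 222 and 201 without the same 3 libraries in turn). The 9 T98G lists became 15 without a filter, 14 with at least 1 CPM in at least 3 libraries, 4 with an estimated correlation and 22 with fry. The 12 U251 lists became 7 with an estimated correlation, and the 10 lists that differed between the lines became 20 with fry. Fits of genes without opposite-strand overlap hold 4176 genes, so their counts are smaller by construction, as are those against a larger fold change. The smaller set is not the whole of the drop, as genes without overlap were also called less often in the main fit. In T98G 28.5% of them were called, against 35.3% of genes with overlap, and in U251 6.76% against 10.1%. For the difference between lines the shares were 23.6% and 30.9%. The cause was not tested for the other moved values. The log2 fold change of PEPD stayed between 3.50 and 4.51 in T98G and between 3.95 and 4.47 in U251 with each library left out. With the replicate number as a block, 2793 genes were called in T98G and 757 in U251. Correlations between PEPD-OE and NC libraries were taken over deviations from their group means. For same-numbered libraries they were 0.060, 0.085 and 0.004 in T98G and -0.076, 0.188 and 0.088 in U251. For differently numbered ones they ranged from -0.107 to 0.039 in T98G and from -0.193 to 0.107 in U251. T98G PEPD-OE replicate 3 correlated best with NC replicate 2. With 3 libraries per group, such correlations do not settle whether replicate numbers pair the samples. Of 5755 comparisons of single named genes with another setting, 422 lost the call, as did 42 of 699 of gene lists, and none of either changed direction. A gene filtered out in a setting, or without an adjusted p there, was not compared. The test against a log2 fold change of 0.5 is not in this tally, and the list tally counts fry as a setting. Leaving out a library gave 3108 of the 5755 comparisons, in part with a library of the other line.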

Other observations

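Counts under names inside coding exons of the other strand tracked those of their partners. Over 160 pairs, the Spearman correlation between the T98G log2 fold change of the noncoding gene and that of its coding partner was 0.424 (highest of 1000 random pairings 0.223), and 32 of the 36 pairs called under both names moved the same way. In U251 it was 0.408 (highest of random pairings 0.247), with 5 of 5. In T98G, TALAM1 (log2 fold change 1.88) and MALAT1 (opposite AP000769.2, 1.66) rose together, and BEST1 (opposite FTH1, 0.90) rose with FTH1 (opposite BEST1, 0.86). Counts under PRKG1-AS1 (opposite DKK1) fell in T98G from 43 to 0, at least 14.2-fold lower, and those under DKK1 (opposite PRKG1-AS1), a secreted Wnt inhibitor, from 35 to 1, a 34.6-fold lower ratio (5.82 to 1407).

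A hypothesis from the T98G correlation of 0.424, whose rule was set before the test, is that both names count reads of the same transcripts. Under it, the change under CCDC152 may be that of SELENOP, which encodes the selenium carrier, rather than of CCDC152. SELENOP itself did not pass in T98G (log2 fold change 0.13, adjusted p = 0.713). In U251 it had 0 counts against 7, at least 2.38-fold lower, beside a decrease under CCDC152 (opposite SELENOP) from 259 ± 8.36 to 78.2 ± 11.4 CPM, but that call for SELENOP was lost in 8 settings (adjusted p = 0.0543 to 0.190). Counting the reads again on the other strand would test this.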
